A study of Mus musculus with 20 samples.

How the data were processed

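Total RNA from whole-cell lysate of the forebrain (cortex and hippocampus) of male C57BL/6 mice aged 1 week was sequenced, per the labels, in 10 wild-type (WT) libraries and 10 libraries of littermates carrying the R306C missense allele of Mecp2. Genotype and replicate number came from the sample titles. The labels describe 10 animals of each genotype and do not say which animals shared a litter, a dissection day or a sequencing run. Other ages, fractions and genotypes of the study were not analysed here.

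The deposited values are raw counts of reads over the exons of 24500 gene symbols, 1 column per library, with no normalization. Per the submitters' processing notes, the authors used Trimmomatic 0.36, STAR 2.5.2b and featureCounts 1.6.0 from Subread with genome build mm10; the notes give neither roles nor parameters. The gene annotation, the strand setting and the handling of reads that match several places are not given in the sources used here. Counts of near-identical genes (globins, histones, ribosomal proteins) and of overlapping genes are therefore uncertain. Among the 11 genes named by rule, Ccdc67 overlaps 4930540M03Rik and Rnls overlaps Mir3970 in the annotation, and the others overlap no other counted gene symbol. Overlaps with genes absent from the counts were not checked. The total count per library ran from 12364241 to 20584737. None of the 90 library pairs within a genotype had identical counts throughout, and over these pairs the chi-square per degree of freedom lay between 1.96 and 16.9, so all 20 libraries were kept as separate samples.

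Gene positions and spans came from a RefSeq table of assembly GRCm38.p6, the assembly of mm10. It held 23535 symbols directly and 876 under an older symbol, and 89 symbols had no entry. Of the genes tested, 37 had no span and stayed out of the comparison by length.

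Differences were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr on genotype, TMM normalization, glmQLFit and glmQLFTest with genotype as the only term, and Benjamini-Hochberg adjustment over the 14539 genes tested, with a threshold of 0.05. CPM values are counts scaled to a common library size with TMM factors. Standard errors are the absolute log2 fold change divided by the square root of the F statistic, and 95% intervals use the degrees of freedom of the same fit.

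The test, the 44 gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule named Mecp2, then genes past the threshold with a mean CPM of at least 1, at most 12 in each direction. Where fewer than 5 passed in a direction, genes of smallest p with a mean CPM of at least 1 filled up to 5, given as values that did not pass. In each list described, up to 4 members of smallest p are named, as are members that passed when adjusted over the list alone. Lists with at least 3 tested members were tested on log2 CPM (prior count 2) with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, and again with the correlation estimated and with fry.

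The long gene score of a library is the mean log2 CPM of genes spanning over 100 kb minus that of genes of 100 kb or less. The maturation score is the mean log2 CPM of genes that rise with forebrain maturation minus that of genes that fall. These scores and 7 measures of library composition were compared by two-sided permutation tests with 100000 resamples. Each alternative changed 1 choice: normalization by DESeq2 size factors or upper quartile, the expression filter, the test (DESeq2 1.42.0, limma voom with quality weights, robust glmQLFit), the threshold, surrogate variables from svaseq (sva 3.50.0), each library left out, the replicate number as a block, and other definitions of the scores. Leaving out libraries with over 1 CPM of Pmch, and a covariate for thalamic genes, were added after seeing the data. A set of 14 hypothalamus genes, with Pmch, Avp, Oxt, Hcrt and Calcr left out because their values had been seen, was likewise chosen after the data were examined.

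The fit was tested on simulated data: counts for the comparison of R306C with WT were drawn from the means, dispersions and library sizes of these libraries, with 50 genes changed at each of 4 fold sizes. Over the 14487 genes tested, the fit recovered 3 of 50 genes at 1.1-fold, 31 of 50 at 1.2-fold, 49 of 50 at 1.5-fold and 50 of 50 at 2-fold, and called 12 unchanged genes. With so many changed genes, the adjusted threshold was easier to reach than in the real comparison, where 1 gene passed. Counts were also drawn separately for each gene, without differences that libraries share. These recovered numbers can therefore overstate what the real comparison would find.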

Results

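Whole-cell total RNA of the forebrain was measured in 10 WT and 10 R306C male mice aged 1 week. MeCP2 is a chromatin protein that binds methylated DNA, and R306C is a missense change in the part of MeCP2 that binds the NCoR co-repressor. The title of the series concerns MeCP2 and highly methylated long genes, and the comparison asks which transcripts differed in R306C forebrain at this early age. Total exon counts averaged 17400000 ± 2477000 in WT and 18360000 ± 1026000 in R306C (SD, n = 10 each). The spread between libraries covers animals of 1 genotype together with any differences in dissection, library or sequencing, which the labels do not separate.

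Mecp2 itself (X, 74026592 to 74085690, mm10) had similar RNA levels in both genotypes. Its exon counts were 145 ± 12.0 CPM in WT and 154 ± 11.7 CPM in R306C (SD, n = 10 each). The log2 fold change of 0.085 ± 0.048 (SE) had a 95% interval from -0.014 to 0.18 and did not pass (adjusted p = 0.9996, edgeR quasi-likelihood test). A missense allele need not alter transcript level, so Mecp2 counts do not check the genotype labels.

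**Figure D1:**
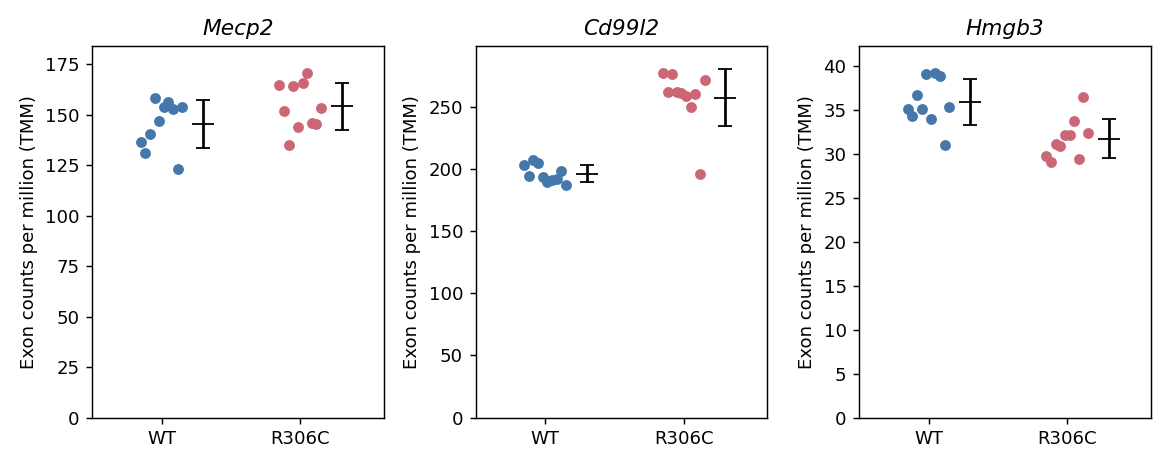
Exon counts in CPM (TMM) of Mecp2, Cd99l2 and Hmgb3, 1 point per library in WT and R306C, with the mean and SD of each group (n = 10) beside the points. Cd99l2 lies between 187 and 207 CPM in WT and between 250 and 277 CPM in 9 R306C libraries, with R306C replicate 9 at 195.5 CPM; the groups overlap for Mecp2 and Hmgb3.

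Cd99l2, which encodes a membrane protein related to CD99, was higher in R306C and was the single gene of 14539 tested to pass the threshold. It lies on X at 71420060 to 71492866, 2.61 Mb before the start of Mecp2. Its level was 196 ± 6.94 CPM in WT and 257 ± 23.2 CPM in R306C (SD, n = 10 each), a 1.31-fold difference (log2 fold change 0.39 ± 0.044, SE; adjusted p = 3.9e-05, edgeR quasi-likelihood test). Cd99l2 exceeded the WT mean in 9 of 10 R306C libraries. R306C replicate 9 had 195.5 CPM, inside the WT range of 187 to 207 CPM. DESeq2 and limma voom also each called 1 gene, Cd99l2.

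No gene was called lower. At an unadjusted p under 0.05 there were 323 genes, 158 higher and 165 lower. Independent tests of 14539 genes without any difference would give about 727. These tests are not independent: random splits of the 20 libraries into groups of 10 gave a median of 501. Of 100 splits, the real one included, 67 had at least 323, so the shortfall from 727 is no result about genotype. Among the genes of smallest p that were higher in R306C without passing, Fam19a2, a secreted neuronal protein gene, had 63.5 ± 5.67 CPM in WT and 72.3 ± 7.38 in R306C (SD, n = 10 each). Ccdc67, Tlr13 and Rnls were near 1 CPM, with log2 fold changes of 0.55 ± 0.14, 0.66 ± 0.20 and 0.54 ± 0.17 (SE). Among those lower without passing, Dmrta2, a transcription factor of the dorsal telencephalon, had 7.54 ± 0.413 CPM in WT and 6.37 ± 0.697 in R306C. Exosc5, a subunit of the RNA exosome, had 9.70 ± 0.664 and 8.47 ± 0.460 CPM, and Hmgb3, a chromatin protein gene, had 35.9 ± 2.62 and 31.8 ± 2.24 CPM. Adamtsl2 and Nppc had log2 fold changes of -0.25 ± 0.071 and -0.30 ± 0.087 (SE). All of these 9 genes had an adjusted p of 0.9996.

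The depth and the spread between libraries bounded most genes closely. Of 13807 genes with a mean CPM of at least 1, 81.3% had a 95% interval of the fold change inside 1.2-fold in either direction, and 98.9% inside 1.5-fold. The biological coefficient of variation was 7.81%. In the simulated counts, differences of 1.1-fold in single genes were mostly not recovered (3 of 50).

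Cd99l2 had neighbours with small unadjusted p around Mecp2. Among 66 other tested genes within 5 Mb of the start of Mecp2, 6 had an unadjusted p under 0.05 and none passed after adjustment. Their share, 9.09%, compares with a median of 2.13%, a 95th percentile of 6.32% and a highest share of 15.4% over 231 other windows of 10 Mb. On the Cd99l2 side, Ids, a lysosomal sulfatase gene, had 321 ± 29.2 CPM in WT and 353 ± 34.3 in R306C, and Naa10 had 31.1 ± 2.32 and 28.8 ± 1.26 CPM. Hmgb3, at 71555917 to 71560673, is the third of these. On the other side of Mecp2, Gdi1, a regulator of Rab proteins, had 793 ± 30.7 CPM in WT and 844 ± 35.6 in R306C, Fam3a had 17.3 ± 0.853 and 18.8 ± 1.27 CPM, and Pls3, an actin-bundling protein gene, had 52.7 ± 6.22 and 45.6 ± 4.72 CPM (SD, n = 10 each). This region was chosen after its values were seen. The fixed list of genes flanking Mecp2 had 12 of 33 members higher and no member past the threshold, adjusted over the list alone (smallest 0.150).

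**Figure D2:**
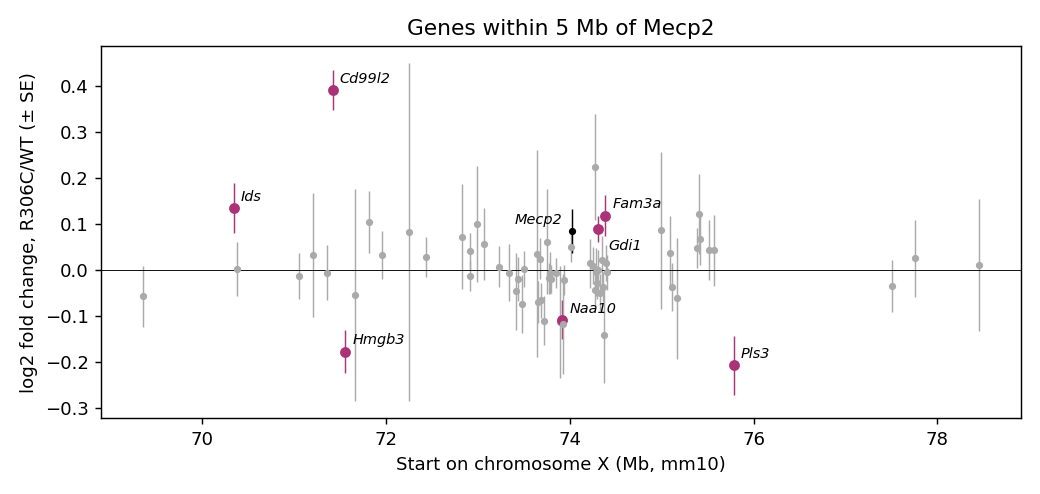
Log2 fold change of R306C over WT with its SE (vertical) for tested genes whose start lies within 5 Mb of the start of Mecp2 on chromosome X (horizontal, Mb, mm10). Larger coloured points have an unadjusted p under 0.05; Cd99l2 at 0.39 is the single gene past the adjusted threshold.

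Long genes as a class did not differ between the genotypes by more than the spread between libraries. The long gene score, over 2235 genes spanning more than 100 kb and 12267 shorter genes, was 0.595 ± 0.0448 in WT and 0.614 ± 0.0440 in R306C (SD, n = 10 each). The difference of 0.019 had a 95% interval from -0.023 to 0.061 (permutation p = 0.345, two-sided). Across 8 classes of span the median log2 fold change ran from -0.016 for 1791 genes under 5 kb to 0.034 for 217 genes over 500 kb, where 72.4% of genes were above 0. In none of the classes did the genotype difference per library pass (adjusted p = 0.588 in each, permutation test, 8 classes). The fixed list of very long genes had 78 of 95 members higher in R306C, with a median log2 fold change of 0.037. It passed with camera at the preset correlation (adjusted p = 4.2e-05), and its adjusted p was 0.844 with an estimated correlation, which was 0.294 between its members. Tenm3, a teneurin adhesion protein gene, had a log2 fold change of 0.13 ± 0.045 (SE), and Tmeff2 had 46.9 ± 2.76 CPM in WT and 50.4 ± 2.54 in R306C; neither passed (adjusted p = 0.9996 over all genes; smallest 0.456 adjusted over the list alone).

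**Figure D3:**
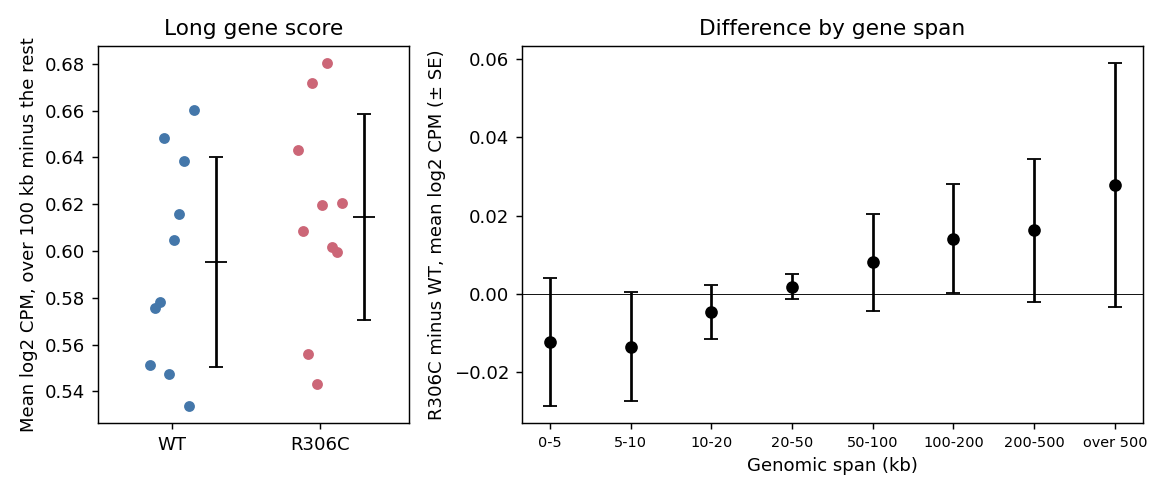
Left, the long gene score of each library (mean log2 CPM of genes over 100 kb minus that of the rest), with the mean and SD of each group (n = 10). Right, R306C minus WT in mean log2 CPM, relative to all genes with a span, for 8 classes of genomic span in kb, with the SE over libraries; the lowest point is -0.014 at 5 to 10 kb and the highest is 0.028 over 500 kb.

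Of 44 gene lists, 8 passed with camera at the preset correlation, and 0 passed with an estimated correlation (smallest adjusted p = 0.844) or with fry (smallest adjusted p = 0.995). Very long genes were 1 of the 8. Of genes of the olfactory bulb and rostral stream, 4 of 18 were higher (median -0.12, camera adjusted p = 8.4e-04, adjusted p = 0.844 with an estimated correlation). Its adjusted p was 0.355 without the 4 libraries that had over 1 CPM of Pmch, a hypothalamic gene. With a covariate for thalamic genes it was 0.0017 (camera). Dlx2, a transcription factor of interneuron precursors, had a log2 fold change of -0.19 ± 0.071 (SE), and Cdhr1 had 63.1 ± 22.7 CPM in WT and 47.9 ± 24.4 in R306C. Of striatal genes, 5 of 22 were higher (median -0.062, camera adjusted p = 0.0133), with the neuropeptide precursors Tac1 at 26.6 ± 2.59 and 24.1 ± 3.12 CPM and Penk at 55.2 ± 6.84 and 49.2 ± 7.43 CPM. Of histone genes, 1 of 22 was higher (median -0.061, camera adjusted p = 0.00119). For both, the adjusted p was 0.844 with an estimated correlation. With single libraries left out, the striatal call ended without WT replicate 4 (adjusted p = 0.130), WT replicate 8 (0.0873), R306C replicate 5 (0.0528) or R306C replicate 10 (0.161). The histone call ended without WT replicate 7 (adjusted p = 0.0963) or WT replicate 9 (0.0714).

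Of erythroid genes, 7 of 8 were higher in R306C (median 0.17, camera adjusted p = 0.0136), with Hbb-bt, a beta globin, at 21.5 ± 4.94 CPM in WT and 26.4 ± 5.42 in R306C. WT replicate 5 stood apart with the lowest mean log2 CPM of these genes in WT (4.34, the next at 4.84), and the call ended without it (adjusted p = 0.130) or without R306C replicate 5 (0.139). All 7 mitochondrially encoded genes were higher (median 0.088, camera adjusted p = 0.0395). With the replicate number as a block, the erythroid (camera adjusted p = 0.0859) and mitochondrially encoded (0.0966) calls both ended. Immediate early genes, which neuronal activity or handling induces, had 9 of 29 members higher (median -0.047, camera adjusted p = 0.0264), with Ier5 at 25.6 ± 1.19 and 23.3 ± 1.75 CPM. These 3 lists had an adjusted p of 0.844 with an estimated correlation. Ribosomal proteins had 19 of 75 members higher (median -0.016, camera adjusted p = 0.0198; adjusted p = 0.964 with an estimated correlation). With single libraries left out, 3 of these calls ended often. Mitochondrially encoded genes lost theirs without any of WT replicates 1, 3, 5, 7 and 9 or R306C replicates 1, 3, 4, 5, 6, 7 and 9 (adjusted p from 0.0507 to 0.395). Immediate early genes did so without any of WT replicates 1, 2, 3 and 9 or R306C replicates 5, 7 and 9 (0.0674 to 0.244), and ribosomal proteins without any of WT replicates 5, 7 and 9 or R306C replicates 1, 2, 4 and 7 (0.0689 to 0.837). No member of these lists passed over all genes or over its list alone.

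MeCP2 partners, DNA methylation machinery and genes reported as MeCP2-sensitive did not pass. Of the partners, 8 of 15 were higher (camera adjusted p = 0.982), with Ncor2, a co-repressor, at 235 ± 16.8 CPM in WT and 225 ± 12.3 in R306C. Of the methylation machinery, 11 of 17 were higher (camera adjusted p = 0.390), with Mbd5 at 35.3 ± 3.04 and 38.0 ± 3.23 CPM. Of the 30 genes reported as MeCP2-sensitive, 9 were higher (camera adjusted p = 0.628). Their median log2 fold change was -0.021. The direction reported for each gene was not used, and camera looks for a shared direction, so opposite changes could cancel. The fry test for changes in either direction did not pass for this list (adjusted p = 0.962). Tac1, the member of smallest p, was lower, at 26.6 ± 2.59 CPM in WT and 24.1 ± 3.12 in R306C. Sgk1, a kinase gene induced by glucocorticoids, was higher, at 72.8 ± 4.19 and 76.6 ± 4.49 CPM.

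The stage of maturation did not separate the genotypes. The maturation score was -0.55 ± 0.21 in WT and -0.54 ± 0.27 in R306C (SD, n = 10 each; difference 0.012, 95% interval from -0.21 to 0.24, permutation p = 0.909, two-sided). Hmgb3 passed among the 46 genes that fall with maturation when adjusted over the list alone (p = 0.0374, edgeR), and did not pass over all genes (adjusted p = 0.9996). None of 7 measures of library composition differed (smallest adjusted p = 0.636, permutation test). Mitochondrially encoded genes took 0.462 ± 0.0558% of counts in WT and 0.484 ± 0.0416% in R306C, and erythroid genes 0.0525 ± 0.00529% and 0.0551 ± 0.00390%.

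Genes of the thalamus and diencephalon, regions that border the dissected cortex and hippocampus, varied widely between libraries of both genotypes. Their mean log2 CPM over 18 genes ran from 3.54 to 4.68, and the list did not pass between genotypes (12 of 18 higher, camera adjusted p = 0.284). It passed at the preset correlation without WT replicate 5 (adjusted p = 0.0383) or without R306C replicate 10 (0.0403), and its adjusted p was 0.964 with an estimated correlation over all libraries. Slc17a6, a glutamate transporter of thalamic neurons, ran from 31.0 to 83.7 CPM across libraries. Avp, the vasopressin precursor, ran from 0.106 CPM to 13.0 CPM. Pmch, a peptide precursor of the lateral hypothalamus, was above 1 CPM in 4 libraries (WT replicate 5 and R306C replicates 3, 7 and 9). Without these libraries Cd99l2 was again the 1 gene called, and the number of lists past the threshold fell from 8 to 3. They include R306C replicate 9, the R306C library with Cd99l2 at the WT level, so this is no independent check of the Cd99l2 call. The olfactory bulb list (adjusted p = 0.355), erythroid genes (0.129), and immediate early, mitochondrially encoded and ribosomal protein genes (0.269 each) lost their calls (camera). Fewer libraries remained in this fit, and all of these lists but the olfactory bulb list also lost their calls with some single libraries left out. The losses can therefore not be tied to Pmch. With a covariate for thalamic genes, by contrast, 7 lists passed. Olfactory bulb (camera adjusted p = 0.0017), erythroid (0.038), mitochondrially encoded (0.044) and ribosomal protein genes (6.6e-04) kept their calls. Immediate early genes did not (0.168).

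**Figure D4:**
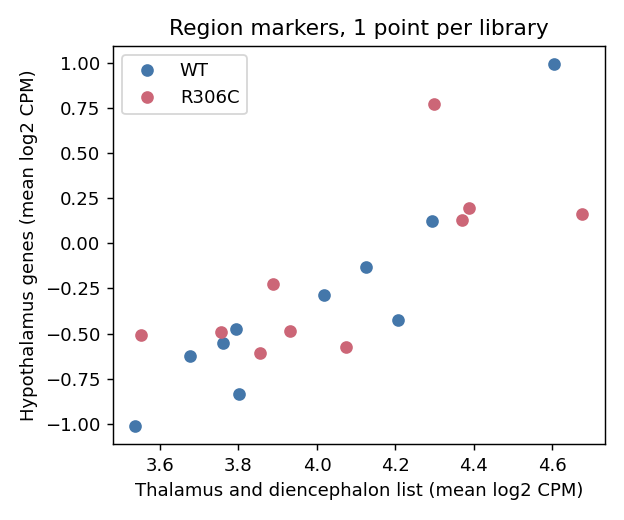
Mean log2 CPM of 18 genes of the thalamus and diencephalon (horizontal) against that of 14 hypothalamus genes (vertical), 1 point per library in WT and R306C. The measures rise together in both genotypes, from 3.54 to 4.68 on the horizontal axis.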

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

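Tests of a carried strain segment, of a swap between libraries and of the relation with hypothalamus genes were chosen only after the result was seen. Within each genotype, 14 of 128 sets of 10 values had 1 library far from the others, where chance gives about 6.4.

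Cd99l2 in R306C had a gap of 0.67 of the group's range below the next library: R306C replicate 9 had 195.5 CPM and the other 9 between 250 and 277 CPM. Cd99l2 lies near Mecp2, so a candidate explanation for its higher level in R306C is a segment of another strain carried along with the mutant allele. The share of neighbouring genes with an unadjusted p under 0.05 exceeded that of 97.8% of the other windows, which this explanation needs. An effect of the R306C protein on Cd99l2 was not tested and stays open.

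For R306C replicate 9, a swap with a WT library is argued against: 0 WT libraries had Cd99l2 inside the range of the other R306C libraries. A single wrong label and a recombination between Cd99l2 and Mecp2 cannot be told apart. On genes chosen without that library, where 0 is the WT mean and 1 the R306C mean, its score was -0.257 on the Cd99l2 side (6 genes, Cd99l2 among them, whose low value prompted the test; -0.307 without it) and 1.09 beyond Mecp2 (3 genes). A wrong label would put the second score with WT, and a recombination with R306C. It lay above the WT range (-0.935 to 0.885) but within 2 SD of the WT mean (-0.014 ± 0.658), and the other R306C libraries began at 0.508, so the genotypes overlap on these 3 genes. They overlap on the Cd99l2 side as well, where WT ran from -0.8575 to 0.9151 and the other R306C libraries from 0.5875 to 1.474. Without Cd99l2 the highest WT score there was 1.139.

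The third pattern is the spread in thalamic genes among libraries. Tissue from next to the dissected forebrain is a candidate explanation: the thalamus score rose with that of 14 hypothalamus genes over the 20 libraries (Pearson r = 0.830, permutation p = 1e-05, the smallest that 100000 resamples give, adjusted p = 3e-05 over 3 relations; Spearman rho = 0.853, permutation p = 1e-05), and r was 0.802 without the 2 libraries farthest from the median. It was 0.921 within WT and 0.731 within R306C. The library of lowest score still had 17 of 18 thalamus genes and 5 of 14 hypothalamus genes above 1 CPM, and of the most abundant thalamus list genes Slc17a6 and Calb2 (46.1 to 120 CPM) varied while Lhx2 (64.8 to 84.9 CPM) did so less. Different stages of maturation cannot be told apart from no relation (Pearson r = -0.110, 95% interval from -0.527 to 0.349, permutation p = 0.644, adjusted p = 0.644; Spearman rho = -0.066, permutation p = 0.783; r = 0.125 without the 2 libraries farthest from the median), and no other biological explanation was tested; the third relation, with log2 total count, had r = -0.221 (permutation p = 0.356, adjusted p = 0.534) and rho = -0.396 (permutation p = 0.086).

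The other values far from their group are given as the gap over the group's range. WT replicate 2 was highest for Tlr13 (0.531). WT replicate 5 was lowest for the share (0.537) and the score (0.549) of erythroid genes. WT replicate 7 was lowest for astrocyte (0.512), microglia (0.487) and synaptic vesicle genes (0.508). R306C replicate 8 was lowest for the share (0.467) and the score (0.576) of mitochondrially encoded genes. R306C replicate 10 was lowest for inhibitory neuron (0.473), ependymal (0.483) and striatal genes (0.520). R306C replicate 1 was lowest for meningeal and perivascular fibroblast genes (0.490), and R306C replicate 7 was highest for Cajal-Retzius genes (0.483).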

How the results depend on the processing

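The alternatives that leave out libraries by Pmch or use thalamic genes as a covariate were chosen after the result was seen. Cd99l2 stayed past the threshold in all 31 alternatives that test it, with log2 fold changes from 0.37 to 0.43 and adjusted p from 6.2e-13 to 0.00226. Mecp2 (0.039 to 0.10, adjusted p from 0.930) and the long gene score (0.012 to 0.027, permutation p from 0.176) never passed. The count of genes stayed at 1 except with 4 surrogate variables, where it was 3 with 736 genes at an unadjusted p under 0.05; the cause was not tested.

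The count of lists, 8 with the preset correlation, was 0 with an estimated correlation, 0 with fry, 3 with surrogate variables, and 3 without the libraries over 1 CPM of Pmch. With the covariate for thalamic genes the count was 7. It ran from 4 (without WT replicate 9 or R306C replicate 5) to 10 with single libraries left out. Of 30 alternatives, very long genes and olfactory bulb genes kept their call in 27 each, histones in 25, erythroid genes in 24, striatal genes in 23, ribosomal proteins in 19, immediate early genes in 18 and mitochondrially encoded genes in 12. Very long genes lost theirs with surrogate variables (adjusted p = 0.142), an estimated correlation and fry. Mitochondrially encoded genes turned direction with surrogate variables (adjusted p = 0.897). The maturation score, never past the threshold, turned to -0.054 with medians and to -0.0064 without the Pmch libraries, and ran from -0.034 to 0.052 with single libraries left out; the cause was not tested.

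With the replicate number as a block, 1 gene (Cd99l2, adjusted p = 4.5e-05) and 6 lists passed, with 666 genes at an unadjusted p under 0.05 against 323 without the block. Mitochondrially encoded (adjusted p = 0.0966) and erythroid genes (0.0859) were not among the 6. The long gene score gave p = 0.219 (exact permutation within pairs). Deviations of libraries sharing a number correlated over 0.1 in 5 of 10 pairs (-0.088 to 0.447). Their mean was 0.169 against -0.018 for other pairs (permutation p = 0.0014), and 8 of 20 libraries correlated best with their own number, a hint from the data and not from the design. Since the labels tie no number to a litter or day and not every pair exceeded 0.1, the block was kept as an alternative. The main fit therefore takes no account of differences shared by libraries of the same number. The 0 composition measures past the threshold stayed 0 without the 10 largest genes. Precision rose with expression: 7.07% of 1528 genes at 1 to 3 CPM had a 95% interval inside 1.2-fold, and 99.1% of 2417 genes at 100 CPM or more.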

Other observations

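The comparison of splits on the thalamus score and the naming of Gdi1 and Pls3 were chosen after the result was seen. With 4 surrogate variables as covariates, Gdi1 (log2 fold change 0.10 ± 0.017, SE, adjusted p = 0.0114, edgeR) and Pls3 (-0.22 ± 0.032, adjusted p = 8.96e-04) passed beside Cd99l2. All 3 genes called in this fit start within 5 Mb of the start of Mecp2, Cd99l2 before it and Gdi1 and Pls3 beyond it. Gdi1 and Pls3 are also 2 of the 6 neighbours with an unadjusted p under 0.05 in the main comparison, so their calls are no independent evidence on the region. Surrogate variables are estimated with genotype protected, which can favour calls, and other splits were not run with them.

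Of 100 splits of the 20 libraries into groups of 10, the real one included, 3 gave at least 1 gene. A count of 1 was thus uncommon. The other splits were drawn at random and not balanced on genotype, so some can hold most libraries of 1 genotype in 1 group. Which genes they called was not recorded, so they do not decide whether chance gives such a count, and chance is not excluded for it. The real split alone had a smallest p as low as 2.7e-09 (edgeR quasi-likelihood test). The highest of the other splits gave 3704 genes. A split with that many calls points to a structure of the libraries other than genotype. The thalamus score does not account for it by itself: that split differed by 0.305 in the score, while a split that differed by 0.418 and another by 0.303 each called 0 genes. At an unadjusted p under 0.05, 67 of the 100 splits had at least the 323 genes of the real one, with a median of 501 over the others. For the lists, 84 of 100 splits, the real one included, gave at least the 8 lists of the real split with the preset correlation. The other splits had a median of 11 lists and at most 23. The real count was thus below that of a typical random split, and chance cannot be excluded for it.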
